A study of Bos taurus with 34 samples.

How the data were processed

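Small RNA libraries from the cell-free fraction of blood were available for 17 dairy cows, 6 classed as healthy and 11 with subclinical endometritis (SCE), each with a library from an early and a late sampling after calving. The sample labels call the samplings day 25 and day 45, while the series' design text gives 21 and 44 days postpartum; the words of the labels are used here. The labels name the tissue as serum and the design text as plasma. Per the labels' protocols, libraries were made from 10 to 20 ng of small RNA with the TruSeq Small RNA kit, by ligating an adapter to each end, reverse transcription, 13 or 16 PCR cycles and gel selection. Which libraries had 13 and which 16 cycles is not given in the sources used here, and the protocol names no molecular identifiers, so counts are of reads after PCR. Intervals of log2 fold changes come from the edgeR fit and include variation between cows, and intervals of shares of miRNAs are Wilson intervals.

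The deposited files hold whole-number counts per mature bovine miRNA, 1 file per library and 800 names per file, of which 6 had no count in any library. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, the genome build was UMD 3.1 and DESeq2 was used. The aligner, the counting tool, its treatment of reads that match several miRNAs, and the miRNA annotation version are not given in the sources used here. The authors applied no normalization that the values show, since totals differ between libraries. The rows stand in different orders in different files and were joined by name, and the species prefix of each name was dropped.

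The day-25 file of healthy cow 3 was identical to the day-45 file of the same cow and carried the title of the day-45 library in its header. It was used as 1 library, at day 45, so 33 of the 34 libraries and 5 healthy cows at day 25 entered the tests. The design had assumed 6 healthy cows at day 25.

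The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filter on low counts and Benjamini-Hochberg adjustment over the miRNAs tested, at an adjusted p of 0.05, two-sided. Standard errors of log2 fold changes were computed as the absolute value divided by the square root of F. Status was compared at each day with 1 library per cow, and over both days on counts summed per cow. Day 45 was compared with day 25 within each status, and the difference of the day effect between statuses was tested over the 33 libraries. The same cow was sampled at both days, so the animal number pairs the libraries. Over the 16 cows with both days the deviations from group means correlated at a median r of 0.25 across miRNAs within a cow, against -0.040 between cows of the same status, with r over 0.1 in 11 cows. For healthy cows 1, 2, 4, 5 and 6 r was 0.46, -0.15, -0.25, 0.084 and 0.19. Of the 16 day-25 libraries, 6 were closest to the day-45 library of their own cow, and these were all from SCE cows. The values thus show little pairing in healthy cows. The fit with the cow as a block was run as an alternative for single miRNAs. List tests used only the fits without the block, so those between days ignored the pairing.

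The 16 miRNA lists, fixed before the data were examined, were red blood cell, platelet, neutrophil and monocyte, lymphocyte, inflammation-induced, liver, striated muscle, epithelium, ciliated epithelium, endothelium and stroma, ovary, brain, lipid metabolism, let-7 family, miR-17-92 and paralogs, and DLK1-DIO3. They stand for cells and tissues that can release RNA into blood and name no cell in a cell-free sample. Some miRNAs are in several lists. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Calls of list members were also adjusted over the list alone. The named miRNAs followed a rule fixed at the same time. It takes, for each comparison, those with adjusted p under 0.05, filled by lowest unadjusted p to 20, the latter given as values and not as changes. It adds the 10 of highest mean CPM, the 2 most abundant members of each list, and members passing over their list alone. Outside the rule, and named after their values were seen, are miR-425-5p, miR-11979, miR-339a, miR-30a-5p, miR-184, miR-1291 and the names of pairs with nearly the same counts. Group means of CPM and the levels in figures are TMM-normalized. Shares of counts, the ranking by mean CPM and the stricter filter used library totals alone. So did the correlations within cows and between libraries and the values scored by the discriminant.

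Status was also predicted with a diagonal linear discriminant on log2 CPM with a prior count of 2, using the 10 miRNAs of lowest edgeR p among the training cows and leaving out each cow in turn. Its p came from 100 permutations of status with the whole procedure repeated. Library totals, miRNAs detected, the share of miR-486, the share of the 10 most abundant miRNAs and haemolysis ratios were compared with exact permutation tests of the mean between statuses and exact sign-flip tests within cows, two-sided, with adjustment over these 24 tests. The haemolysis ratio is log2 of miR-451 over miR-23a, each count plus 0.5; the planned form used CPM, and counts were used in its place. The other form, also fixed before the data were examined, was miR-486 over miR-23a.

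On counts simulated from these libraries, the edgeR test of status at day 25 called 13.8% of miRNAs changed 2-fold, 65.5% of those changed 4-fold and 93.5% of those changed 8-fold, and 3.87% of its calls were false. Over both days it called 25.1%, 85.0% and 96.3%, and for day 45 against day 25 in SCE cows 34.5%, 89.4% and 100%. These shares are of changed miRNAs that passed the filter. miRNAs were drawn independently and many were changed at once. At day 25, 5 simulations held 189, 174 and 169 tested miRNAs changed 2-, 4- and 8-fold, with a mean of 377.4 tested per simulation. The shares need not hold for data with few changes or with miRNAs that vary together. Other settings fixed in advance were DESeq2 size factors, no filter, a stricter filter (CPM of at least 10 in at least 6 libraries), the DESeq2 1.42.0 Wald test, the haemolysis ratio as a covariate, all libraries in 1 fit, limma voom with the cow as a random effect, the block, each cow left out, and other sizes and selection of the discriminant. Chosen after seeing the data were the files as deposited, 1 name of each pair with nearly the same counts (differences summed over libraries under 1% of the larger total, for names with at least 1000 counts), leaving out SCE cow 10, thinning every library to 3000000 counts without SCE cow 10, robust dispersion, and the ratio of miR-486 to miR-23a as a covariate. The DESeq2 Wald test took all miRNAs with a count. After its default filters it gave an adjusted p to 522 miRNAs at day 25, 748 at day 45 and 286 over both days. Its adjustment is thus over other sets than that of edgeR. No genomic coordinates are given, since the annotation at hand is of assembly ARS-UCD2.0 and the counts of another build. The annotation was used only to see which miRNA genes overlap.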

Results

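Circulating miRNAs were counted in blood of 17 dairy cows to ask whether cows with subclinical endometritis (SCE), an inflammation of the uterine lining without outward signs, differ from healthy cows, and whether early levels can tell the statuses apart. Libraries numbered 5 for healthy cows at day 25, 6 for healthy cows at day 45, and 11 for SCE cows at each day. The day-25 file of healthy cow 3 was a copy of its day-45 file and was counted as 1 sample. Total counts ranged from 678389 to 28872153 per library. Means were 14555228 ± 6931178 counts in healthy cows at day 25 (SD, n = 5), 16759556 ± 7915155 in healthy cows at day 45 (SD, n = 6), 8432112 ± 3732281 in SCE cows at day 25 and 10074620 ± 5221098 in SCE cows at day 45 (SD, n = 11 each). Both libraries of SCE cow 10 were shallow, at 1343401 and 678389 counts.

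miR-486, a miRNA abundant in red blood cells, was the most abundant miRNA by its mean over libraries. It had the highest count in 4 of 5 healthy and 5 of 11 SCE libraries at day 25 and in 6 of 6 healthy and 7 of 11 SCE libraries at day 45, while miR-191 lay above it in 1 healthy and 6 SCE libraries at day 25 and in 4 SCE libraries at day 45. It took 50.3 ± 20.7% of counts in healthy cows at day 25 (SD, n = 5), 46.2 ± 21.0% in healthy cows at day 45 (SD, n = 6), 25.4 ± 25.1% in SCE cows at day 25 and 31.3 ± 17.1% in SCE cows at day 45 (SD, n = 11 each). By mean it was followed by miR-191, with 11.6 ± 6.34% of counts in healthy (SD, n = 6) and 14.9 ± 10.7% in SCE cows (SD, n = 11) at day 45, and then by miR-3600, miR-22-3p, miR-192, which is rich in liver, miR-423-5p, miR-21-5p, miR-27b, miR-10b and miR-142-5p, which is specific to blood cells. The counts of miR-3600 and miR-22-3p differed by less than 1% of the larger total, summed over libraries, so the reads of the 2 names cannot be told apart. The same held for let-7b and miR-3596, miR-148c and miR-152, miR-199a-3p and miR-3604, miR-2285q and miR-2285z, miR-3065 and miR-338, and miR-6529a and miR-6529b, and values of these names are uncertain.

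Some library measures had low unadjusted p between statuses, and none passed adjustment over the 24 tests. The lowest p belonged to the share of the 10 most abundant miRNAs, at -10.9 percentage points in SCE minus healthy cows at day 25 (exact permutation p = 0.027) and -7.03 at day 45 (exact permutation p = 0.053), each with adjusted p = 0.214. The difference in miRNAs detected was 65.4 at day 25 (exact permutation p = 0.119) and 16.5 at day 45 (exact permutation p = 0.728). SCE minus healthy totals were -6123116 counts at day 25 (exact permutation p = 0.034) and -6684935 counts at day 45 (exact permutation p = 0.0496), both with adjusted p = 0.214. The log2 ratio of miR-451 to miR-23a, a measure of red blood cell RNA, differed by -0.79 at day 25 (exact permutation p = 0.469) and by -0.98 at day 45 (exact permutation p = 0.237). With miR-486 in the place of miR-451 the difference was -3.31 at day 25 (exact permutation p = 0.031) and -2.02 at day 45 (exact permutation p = 0.045), with adjusted p = 0.214 for each. Title numbers ran from 13 to 24 in healthy and from 31 to 52 in SCE libraries without overlap, so an order of preparation that followed them could not be separated from status.

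**Figure D1:**
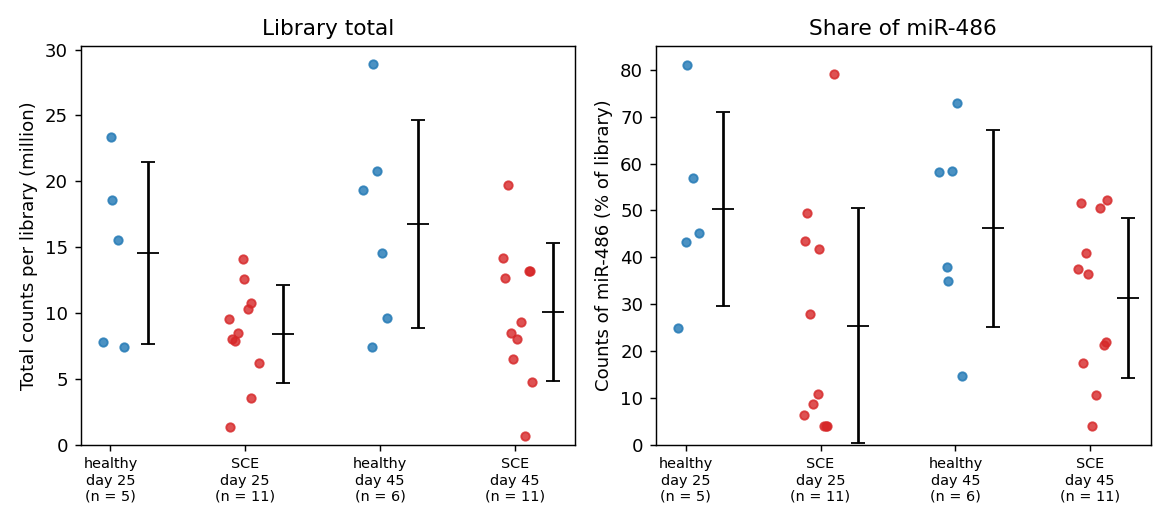
Total counts per library (left, axis in units of 1e+06 counts) and miR-486 as a percent of counts (right) for each of 33 libraries, by status and day. Points are libraries and bars are mean ± SD; healthy means were 14555228 and 16759556 counts at day 25 and day 45 against 8432112 and 10074620 in SCE cows.

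At day 25, 1 of 372 miRNAs tested rose in SCE cows and none fell. miR-425-3p, the minor arm of a hairpin whose locus also gives miR-191, rose from 32.5 ± 8.67 CPM in healthy (SD, n = 5) to 152 ± 79.8 CPM in SCE cows (SD, n = 11), a log2 fold change of 2.23 with SE 0.46 (edgeR adjusted p = 0.036). All 11 SCE cows lay above every healthy cow. The other arm, miR-425-5p, had a log2 fold change of 0.46 with SE 0.35. At an unadjusted p under 0.05 stood 75 miRNAs, 43 higher and 32 lower, where 18.6 were expected by chance. DESeq2 called 14 of the 522 miRNAs to which it gave an adjusted p, 11 higher and 3 lower. The edgeR call of miR-425-3p ended when any of 10 of the 16 cows was left out, among them healthy cows 1, 2, 4 and 6 and SCE cows 11, 12, 14, 15, 16 and 17, with adjusted p up to 0.125 and log2 fold changes from 2.09 to 2.39 over all 16 fits. Without SCE cow 7 there were 6 up and 1 down, and without healthy cow 5 there were 2 up and 1 down. Without SCE cow 13 or 8 there were 4 and 3 up. It also ended with the ratio of miR-486 to miR-23a as a covariate, where the log2 fold change was 1.20 (edgeR adjusted p = 0.252). With the ratio of miR-451 to miR-23a as a covariate it was kept, and miR-486 was also called, lower in SCE cows.

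Further miRNAs of low p at day 25 are given as values, since edgeR did not call them. Among members of the endothelium and stroma list, miR-195 had a log2 fold change of 2.75 (SE 0.69) and miR-497 of its cluster 2.09 (SE 0.53), with edgeR adjusted p = 0.069 for each. miR-145, rich in smooth muscle, stood at 1.37, while miR-10a and miR-10b of the HOX clusters stood at -1.42 and -1.92. Adjusted over the list alone, miR-195, miR-497, miR-145, miR-10a and miR-10b passed, 3 up and 2 down. Over all miRNAs tested edgeR called none of them. Over the miRNAs left by its own filters DESeq2 called miR-195 and miR-497. Of its members 6 were higher and 7 lower. Fry's mixed test, which asks whether members differ in either direction, gave adjusted p = 0.045 for this list. That test does not compare the list with other miRNAs, of which many had low p. It does not show a change particular to this list. miR-27a-3p of the neutrophil and monocyte list (1.34) and miR-151-3p of the platelet list (-1.24) each passed adjusted over the list alone. Over all miRNAs tested their edgeR adjusted p were 0.185 and 0.117, and DESeq2 called both over the miRNAs left by its own filters. Other log2 fold changes were 3.33 for miR-2299-3p, 2.88 for miR-30b-5p, 1.79 for miR-30c, 2.68 for miR-345-5p, 2.80 for miR-188, 2.24 for miR-193a-3p, 2.94 for miR-2483-5p, 1.57 for miR-628, 1.37 for miR-151-5p, -2.13 for miR-2389, -0.85 for miR-1839, -1.26 for miR-193b and -1.13 for miR-320a. The inflammation-induced miR-21-5p stood at -1.64, but at 0.38 without healthy cow 4.

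No list was called by camera at day 25, the smallest adjusted p being 0.442. Of the tested members, those with a higher value in SCE cows were 4 of 12 for red blood cell, 8 of 14 for platelet, 6 of 9 for neutrophil and monocyte, 8 of 11 for lymphocyte, 3 of 11 for inflammation-induced and 3 of 10 for liver. They were 2 of 5 for striated muscle, 6 of 7 for epithelium, 4 of 7 for ovary, 3 of 6 for brain, 5 of 12 for lipid metabolism, 3 of 10 for the let-7 family, 6 of 15 for miR-17-92 and paralogs and 6 of 13 for DLK1-DIO3. The ciliated epithelium list had too few tested members. For striated muscle, endothelium and stroma, brain and DLK1-DIO3 the median, the mean and the direction of the test differed in sign. Among abundant list members the log2 fold changes were -0.83 for miR-92a, -1.19 for miR-25, -0.32 for miR-181a, -0.76 for miR-148a, -0.44 for miR-375, 0.71 for miR-141, -0.31 for let-7f, -0.72 for let-7i and -0.27 for miR-127.

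At day 45, edgeR called none of 382 miRNAs, with 39 at an unadjusted p under 0.05 (21 higher, 18 lower) where 19.1 were expected by chance, and DESeq2 called 1, miR-150. The 39 became 25 without SCE cow 16 and 63 without healthy cow 6, the extremes over cows left out. miR-150, a miRNA of mature lymphocytes, was at 435 ± 350 CPM in healthy (SD, n = 6) and 2642 ± 3453 CPM in SCE cows (SD, n = 11), a log2 fold change of 2.60 with SE 0.70 (edgeR adjusted p = 0.277), and it passed adjusted over the list alone. miR-425-3p stood at a log2 fold change of 1.68 with SE 0.49 (edgeR adjusted p = 0.277), with 10 of 11 SCE cows above every healthy cow. As a group, the lymphocyte list was higher in SCE cows, with 11 of 11 members higher and a median log2 fold change of 0.59 (camera adjusted p = 0.0092), but adjusted p = 0.665 with an estimated correlation. By edgeR no single member passed over all miRNAs, while DESeq2, and edgeR with the ratio of miR-451 to miR-23a as a covariate, called miR-150 alone. miR-28 was at 0.99, miR-29b at 1.23, miR-29c at 0.94 and the most abundant, miR-181a, at 0.01 (at -0.00191 with DESeq2 size factors). Other lists had most members on 1 side without being called: epithelium with 7 of 7 members higher (median 0.83, camera adjusted p = 0.419), brain with 6 of 6 higher (median 0.37, camera adjusted p = 0.501), red blood cell with 8 of 12 lower (camera adjusted p = 0.125) and DLK1-DIO3 with 11 of 16 lower (camera adjusted p = 0.168). Further values were 2.09 for miR-145, 1.53 for miR-30b-5p, 1.58 for miR-505, 1.47 for miR-138, 1.41 for miR-296-5p, 1.53 for miR-365-3p, 3.16 for miR-2468, -1.65 for miR-11971, -1.45 for miR-10225a, -1.17 for miR-182, -1.60 for miR-10b, -1.27 for miR-99b, -1.24 for miR-100 and -1.37 for miR-486. miR-103 and miR-107, 2 relatives that act in lipid and glucose metabolism, were at -0.85 and -1.13.

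**Figure D2:**
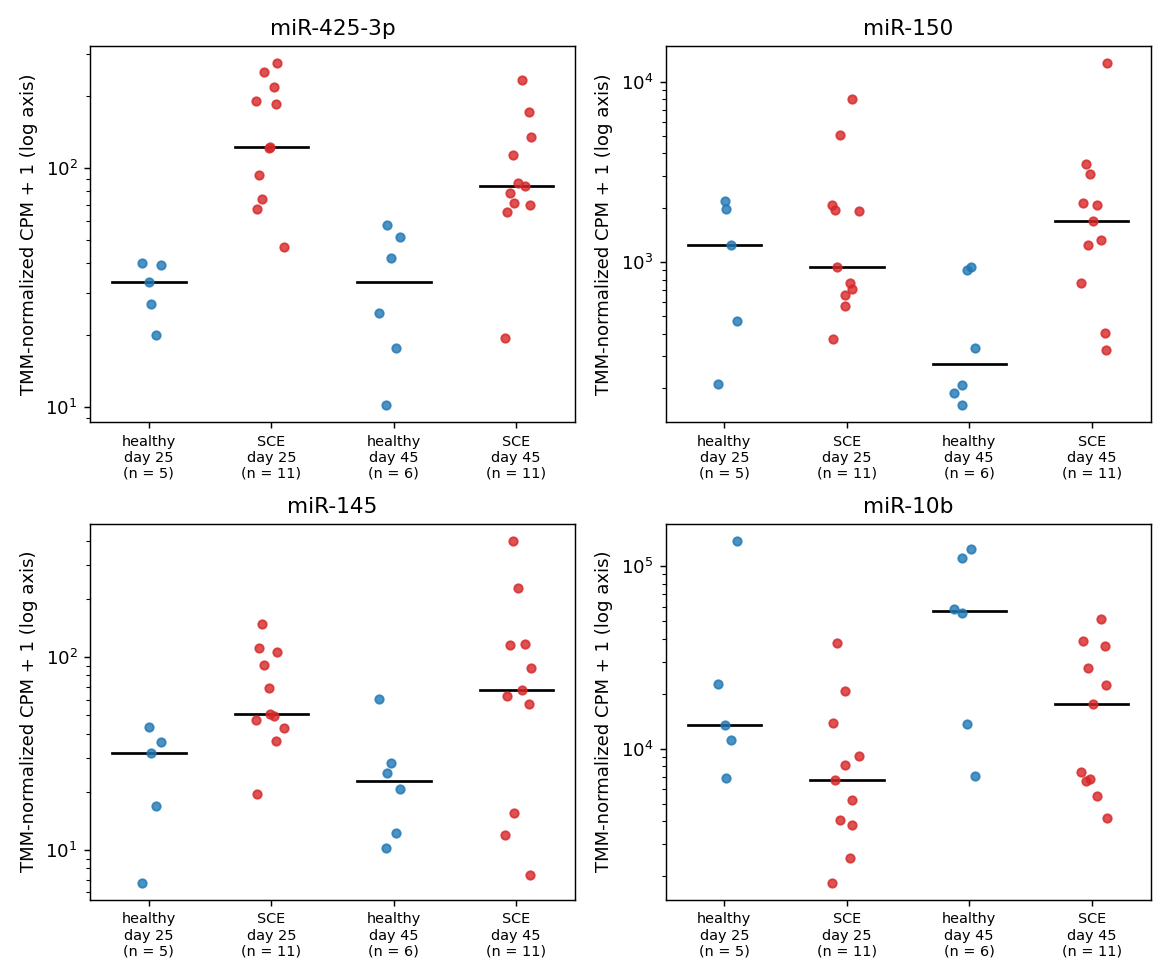
TMM-normalized CPM plus 1, on a log axis, of 4 miRNAs in each library, by status and day, with a line at the median. At day 25 all 11 SCE libraries lie above the 5 healthy libraries for miR-425-3p, the only one of the 4 that edgeR called there.

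Over both days, with counts summed per cow, 1 of 418 miRNAs rose and none fell in SCE cows. miR-425-3p rose from 31.0 ± 16.3 CPM in healthy (SD, n = 6) to 129 ± 70.1 CPM in SCE cows (SD, n = 11), a log2 fold change of 2.06 with SE 0.43 (edgeR adjusted p = 0.033), and 10 of 11 SCE cows lay above every healthy cow. It was followed by miR-10b at a log2 fold change of -1.70 with SE 0.41 (edgeR adjusted p = 0.079) and miR-30b-5p at 2.14 with SE 0.57 (edgeR adjusted p = 0.141). In all, 69 miRNAs had an unadjusted p under 0.05, 42 higher and 27 lower, against 20.9 expected by chance. DESeq2 called 15 of the 286 miRNAs to which it gave an adjusted p, 13 higher and 2 lower. The 69 became 55 without SCE cow 16 and 111 without healthy cow 6, the extremes over cows left out. The edgeR call of miR-425-3p ended without healthy cow 1 or 2 or SCE cow 15 or 16, with adjusted p = 0.076, 0.087, 0.060 and 0.055. That none fell also rests on single cows: 2 rose and 7 fell without SCE cow 9, and 8 rose and 2 fell without SCE cow 7. Without healthy cow 6 the call became 3 up, and without SCE cow 10 it became 2 up and 1 down. Without healthy cow 3 it became 2 up, and without healthy cow 4 or SCE cow 13 it became 1 up and 1 down. It also ended with the ratio of miR-451 to miR-23a as a covariate, where the log2 fold change was 1.86 (edgeR adjusted p = 0.105), and with the ratio of miR-486 to miR-23a, where it was 1.19 (edgeR adjusted p = 0.989).

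The lymphocyte list was higher over both days, with 10 of 11 members higher (camera adjusted p = 0.026), but adjusted p = 0.805 with an estimated correlation. Epithelium, with 6 of 7 members higher (median 0.87), and brain, with 7 of 8 higher (median 0.29), leaned the same way and were not called (camera adjusted p = 0.505 and 0.643). Adjusted over the lymphocyte list alone, its members miR-150 (log2 fold change 1.66), miR-28 (1.02), miR-29b (1.03) and miR-29c passed. Over all miRNAs tested edgeR called none of them. Adjusting over the 286 left by its own filters, DESeq2 called miR-28 and miR-29c. Of the endothelium and stroma list miR-145 (1.69), miR-195 (1.27), miR-497 (1.36) and miR-10b passed adjusted over the list alone, 3 up and 1 down. Over all miRNAs tested edgeR called none of them, while DESeq2 with its own filters called miR-145, miR-497 and miR-10b. For this list fry's mixed test gave adjusted p = 0.046. miR-193a-3p of the liver list (1.92) and miR-138 of the brain list (1.46) also passed over their lists alone. DESeq2 with its own filters called both, and edgeR over all miRNAs tested called neither. Of the red blood cell list 3 of 13 members were higher and 10 lower (camera adjusted p = 0.083), with miR-486 at a log2 fold change of -1.44 and miR-182 at -1.08. Further values were 2.01 for miR-345-5p, 1.54 for miR-505, 2.09 for miR-188, 1.62 for miR-2299-3p, 1.87 for miR-2468, 2.43 for miR-24, -1.23 for miR-10225a and -1.24 for miR-11971.

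In healthy cows, no miRNA of 345 changed from day 25 to day 45 by edgeR, and none by DESeq2. At an unadjusted p under 0.05 stood 10, against 17.2 expected by chance if libraries were independent. When days were exchanged within cows, the median was 16. The 10 became 2 with the cow as a block, and 6 to 24 when each cow was left out. List tests between days took the libraries as unpaired. The endothelium and stroma list was higher at day 45, with 12 of 13 members higher and a median log2 fold change of 0.84 (camera adjusted p = 9.6e-05), but adjusted p = 0.474 with an estimated correlation. Its most abundant members, miR-10b and miR-10a, stood at log2 fold changes of 0.96 and 0.03 (miR-10a at -0.19 with DESeq2 size factors) and those of low p, miR-195 and miR-497, at 1.80 and 1.12. miR-195 was higher in 5 of 5 cows with both days. The DLK1-DIO3 list, an imprinted cluster active in placenta and muscle, was higher with 12 of 15 members (camera adjusted p = 0.0015), but adjusted p = 0.520 with an estimated correlation. Its miR-411a was at 1.40 and miR-127 at 0.40. Striated muscle had 5 of 5 members higher (median 0.60) and was not called (camera adjusted p = 0.687). Further values were -1.69 for miR-197, -2.45 for miR-328, -3.23 for miR-11978, -1.51 for miR-1343-3p, 2.62 for miR-411c-5p, -1.27 for miR-193b and -1.40 for miR-150.

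In SCE cows, none of 346 miRNAs changed between the days by edgeR, and none by DESeq2. At an unadjusted p under 0.05 stood 14, against 17.3 expected by chance if libraries were independent. The same cows gave both days, and exchanging days within cows gave a median of 7. The 14 became 24 with the cow as a block, and 6 to 27 when each cow was left out. Here too the list tests took the libraries as unpaired. The miR-17-92 and paralogs list, clusters linked to cell proliferation, was higher at day 45, with 13 of 15 members higher and a median log2 fold change of 0.34 (camera adjusted p = 2.3e-04), but adjusted p = 0.632 with an estimated correlation. Its most abundant members, miR-92a and miR-25, stood at 0.08 and 0.15, and those of low p, miR-106a and miR-19b, at 0.81 and 0.80. DLK1-DIO3 had 11 of 13 members higher (median 0.21) and was not called (camera adjusted p = 0.382). miR-133a, a muscle miRNA, was at a log2 fold change of 2.35 with SE 0.74 (edgeR adjusted p = 0.705), higher in 8 of 11 cows, and passed adjusted over the list alone. Further values were 1.40 for miR-101, 1.63 for miR-143, 1.11 for miR-21-5p, 0.60 for miR-140, 1.61 for miR-185, -1.22 for miR-345-5p, -1.17 for miR-4286, -0.84 for miR-1306 and -0.68 for miR-197.

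The change from day 25 to day 45 was not shown to differ between SCE and healthy cows for any of 406 miRNAs by edgeR, and for none by DESeq2. At an unadjusted p under 0.05 stood 7, against 20.3 expected by chance if libraries were independent. Reassigning statuses over cows gave a median of 9. The lowest p belonged to miR-195, with a difference of -2.21 log2 units and SE 0.83 (edgeR adjusted p = 0.988), followed by miR-2284h-5p at 2.54, miR-9 at 2.26, miR-7859 at -3.43, miR-365-5p at 2.73, miR-2299-3p at -2.31 and miR-193b at 1.53. No list was called, the smallest camera adjusted p being 0.394. List tests by fry, which ask whether members move 1 way on balance, gave no adjusted p under 0.05 in any of the 6 comparisons, the smallest being 0.118.

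Across the 362 miRNAs tested at both days, the log2 fold changes of SCE against healthy at day 25 and day 45 correlated at Pearson r = 0.582 and Spearman rho = 0.591. miRNAs are not independent replicates, and the same cows enter both days. When status was permuted over cows with both days kept together, the median r was 0.294 and 7 of 100 permutations gave as large an r (permutation p = 0.079). For rho the permutation p was 0.089. The covariance was 0.383 against a permuted median of 0.115 (permutation p = 0.030). At both days 16 miRNAs had an unadjusted p under 0.05, each with the same sign at both, against 7.77 for independent lists and a permuted median of 2 (permutation p = 0.0495). Of these, miR-425-3p, miR-30b-5p, miR-497, miR-145, miR-188, miR-193a-3p, miR-138, miR-505, miR-29b, miR-29c and miR-339a were higher in SCE cows, and miR-10b, miR-103, miR-30a-5p, miR-184 and miR-1291 were lower.

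**Figure D3:**
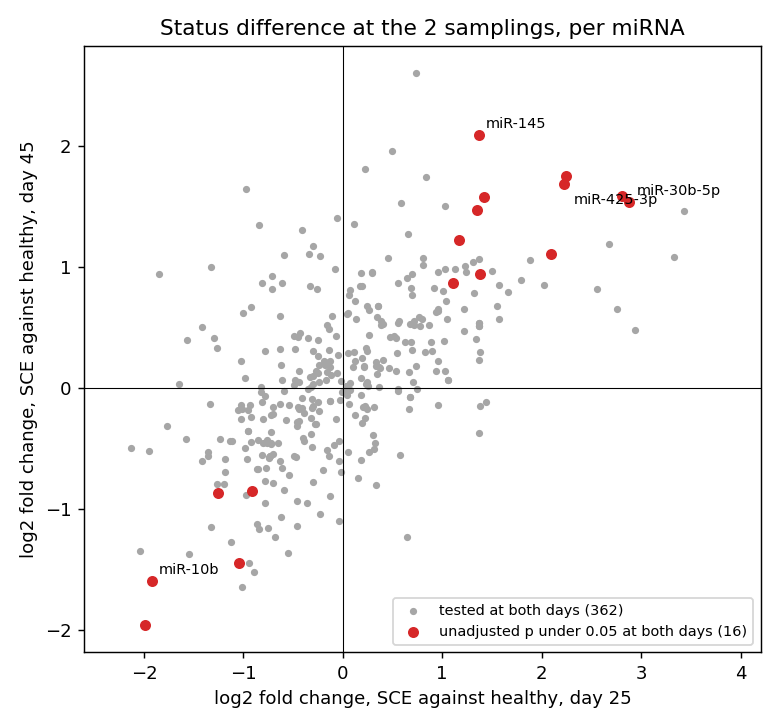
Log2 fold change of SCE against healthy cows at day 25 (horizontal) and day 45 (vertical) for the 362 miRNAs tested at both days; red points are the 16 with an unadjusted p under 0.05 at both. Every red point has the same sign at both days, and r over all points is 0.582.

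A discriminant of 10 miRNAs, chosen anew without the cow to be classed, gave an area under the ROC curve of 0.855 at day 25, with 10 of 11 SCE and 3 of 5 healthy cows classed correctly. Of 100 permutations 5 gave as large an area (permutation p = 0.059). At day 45 the area was 0.682, with 7 of 11 SCE and 5 of 6 healthy cows classed correctly, and 16 of 100 permutations gave as large an area (permutation p = 0.168). The permuted medians were 0.455 and 0.432. With miRNAs chosen on all cows before the cow was left out, which lets the classed cow choose its own predictors, the area was 0.891 at day 25 and 0.909 at day 45. The values scored were scaled by library total without TMM, so the share of miR-486 can affect them.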

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

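The 2 healthy groups were small enough for a test of single outlying libraries. In 16 such tests, over totals, miRNAs detected, the shares of miR-486 and of the 10 most abundant miRNAs, both haemolysis ratios, miR-425-3p and the correlation to other libraries, no library stood apart from its group, where chance gives about 1 in 20. No miRNA moved 1 way between the days in all 5 healthy cows with both days and the opposite way in all 11 SCE cows. Such a rule needs all 16 cows to agree, so finding none does not show that the day effects are alike.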

How the results depend on the processing

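Calls at day 25 numbered 1, and became 4 with DESeq2 size factors, 6 with no filter, 14 with the DESeq2 Wald test, 2 with the haemolysis ratio as a covariate and 2 with all libraries in 1 fit. The 2 with the haemolysis ratio were miR-425-3p, higher, and miR-486, lower. Over both days 1 call became 2 with no filter, 2 with the stricter filter, 15 with the DESeq2 Wald test and 0 with the haemolysis ratio. At day 45, 0 calls became 1 with DESeq2 and 1 with the haemolysis ratio, and for the difference of the day effect 0 became 1 with no filter. Of alternatives chosen after seeing the data, day 25 gave 4 with 1 name per pair and 2 after thinning. Both days gave 0 with the miR-486 ratio and 3 without SCE cow 10. Thinning, which also left out that cow, gave the same 3 over both days, so they cannot be credited to thinning. With the miR-486 ratio the count at day 25 was also 1, but the miRNA was miR-11979 and not miR-425-3p. The cause was not tested, except that thinning, leaving out cows or names and filtering change what is tested. Leaving out each cow gave 0 to 7 calls at day 25, 0 to 10 over both days (10 without SCE cow 7, 8 higher and 2 lower; 9 without SCE cow 9, 2 higher and 7 lower) and 0 in the other comparisons refitted.

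The replicate block, with the cow as a factor, gave 0 calls in healthy cows, in SCE cows and for the difference of the day effect, and changed no call of a single miRNA. Lists were not tested with the block. With an estimated correlation the lists called fell from 1 to 0 at day 45 and over both days, from 2 to 0 in healthy cows over time and from 1 to 0 in SCE cows over time. The area under the curve was 0.909 at day 25 with 5 miRNAs, 0.782 with 20 and 0.891 with selection on all cows, and 0.742, 0.773 and 0.909 at day 45. With miR-486 in the haemolysis ratio the status difference was -3.31 at day 25 and -2.02 at day 45, both then past 0.05 unadjusted, and the day difference in healthy cows was -0.16 against 0.62. With the stricter filter r between the days was 0.639.

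Of 3250 single values of named miRNAs under alternatives, 3122 kept direction and side of the threshold, 76 came to pass it, 17 no longer passed it and 35 turned. With the miR-486 ratio these were, at day 25, miR-30c (-0.18), miR-375 (0.37) and miR-127 (0.90, and 0.0262 with the haemolysis ratio), miR-486 at day 45 (0.17) and over both days (0.14), and miR-92a in SCE cows over time (-0.0787). miR-181a at day 45, at 0.01, turned with DESeq2 size factors (-0.00191), DESeq2 (-0.00189), no filter (-0.0311), the stricter filter (-0.0615), the miR-486 ratio (-0.0879) and all libraries in 1 fit (-0.0474). In healthy cows over time miR-10a, at 0.03, turned with DESeq2 size factors (-0.19), DESeq2 (-0.20), thinning (-0.0216) and the files as deposited (-0.27). miR-34a turned with the files as deposited in healthy cows over time (-0.000152) and in the difference of the day effect (0.20), and there with the block (0.14). Ranges over cows left out that cross 0 were, at day 25, -2.04 to 0.38 for miR-21-5p and -0.62 to 0.44 for let-7f (both above 0 without healthy cow 4), -0.69 to 0.17 for miR-375 (above 0 without healthy cow 2) and -0.54 to 0.0554 for miR-127 (above 0 without healthy cow 1). Others were -0.0941 to 0.23 for miR-181a at day 45; -0.42 to 0.95 for miR-10a in healthy cows over time; and -0.10 to 0.39 for miR-92a and -0.0413 to 0.61 for miR-25 in SCE cows over time. DESeq2 size factors moved the median log2 fold change from 0.01 to -0.10 in healthy cows over time, from -0.11 to 0.06 in SCE cows over time and from 0.01 to 0.18 for their difference. Depth limits SCE cow 10 most, and 2-fold changes were mostly missed in simulation.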

Other observations

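Tests chosen after results were seen were those of title numbers, of overlapping miRNA genes, of miR-425-3p with the miR-451 ratio, whose lost call had been seen, and those with the miR-486 ratio as a covariate or for slopes, taken up because the 2 haemolysis ratios had differed, and the counts of shared miRNAs. Counts of calls with the miR-451 ratio were also known before its share at day 25 was computed. The predictions gave bounds for point values. That a value must clear its bound by its whole 95% interval was added after 1 of them, 12.6% against a bound of 10%, had been seen; by point values alone that value and both covariate fits of miR-425-3p would count against their explanations. Intervals of shares treat miRNAs as independent, which they are not, so they are only a rough spread.

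Chance was weighed by regrouping the cows. At day 25, 2 of 100 splits, the real one included, gave 75 or more miRNAs at an unadjusted p under 0.05. The highest other split gave 88. Such a count was thus rare among the splits drawn, which makes chance less likely for it. Chance is not excluded, since only 100 of 4368 possible splits were used and the counts weighed here were not adjusted for their number. For the call, 8 of 100 splits gave 1 call or more (highest 5), so chance was not excluded there. Nor was chance excluded for the 39 miRNAs at day 45 (15 of 100 splits as large, highest 78), for the 69 over both days (8 of 100, highest 89) or their 1 call (6 of 100, highest 16), for 10 in healthy cows over time (19 of 32 exchanges of days within cows, highest 44), for 14 in SCE cows over time (22 of 100, highest 26) or for 7 in the difference of the day effect (59 of 100, highest 55). Splits with several times the real number of calls may point to a structure among the cows other than status or to miRNAs that vary together. Within lists, the correlation estimated over both days ran from -0.037 for striated muscle to 0.81 for epithelium. Whether either of the 2 gave such splits was not tested.

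The excess of low p at day 25 covered 20.2% of miRNAs. Library totals and red blood cell RNA as measured by miR-451 do not account for it alone. With libraries thinned to 3000000 counts 20.1% of 288 miRNAs were at p under 0.05 (Wilson 95% interval 15.9 to 25.1%). The share was 18.8% of 372 with the miR-451 ratio as a covariate (15.2 to 23.1%). Of these 58 and 70 miRNAs, 49 and 54 were among the 75 of low p without the change, 17% (13.1 to 21.8%) and 14.5% (11.3 to 18.5%) of those tested. Thinning evened totals with miR-486 counted in. The mean share of miR-486 at day 25 was 50.3% in healthy and 25.4% in SCE cows. Depth left for other miRNAs was thus not evened, and it stays open. With the miR-486 ratio 12.6% were at p under 0.05 (9.64 to 16.4%), and 18 of these 47 were among the 75, 4.84% of those tested (3.08 to 7.52%). The bound of 5% was set for all miRNAs of low p and not for the shared ones, so the 4.84% cannot be held against it. The interval of the 12.6% reaches under the bound of 10%, which leaves RNA that varies with miR-486 open. That ratio differs between statuses, so adjusting for it can also remove an effect of status. Order of preparation cannot be told apart from status, since 0 libraries had a title number inside the range of the other status.

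A candidate explanation for the difference over both days is a gradient that also runs among SCE cows. Across miRNAs, slopes on the miR-486 ratio within SCE cows alone correlated with the fold change of SCE against healthy at r = -0.648, and 1 of 1000 permutations of the ratio gave as low a value, at -0.667 (permutation p = 0.0020). Of the 69 miRNAs at p under 0.05, miR-486 and miR-23a, which form the ratio, were left out, and 60 of the other 67 had a slope opposite in sign to their fold change. The share over all miRNAs was not computed, so these are not shown to differ from the rest. With the ratio as a covariate 12 of 418 were at p under 0.05, 7 of them among the 69. The gradient may be red blood cell RNA, ligation or amplification that favours miR-486, or cow biology; these were not separated, and status as a biological cause of it was not tested.

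For miR-425-3p over both days, library totals alone do not account for the rise. Thinning evened totals with miR-486 counted in, so depth left for other miRNAs stays open. After thinning the log2 fold change was 2.18 (95% interval 1.26 to 3.09), above a bound of 0.5 times its unthinned value. It was 1.86 (0.86 to 2.86) with the miR-451 ratio and 1.19 (0.26 to 2.12) with the miR-486 ratio; both intervals reach under that bound, so red blood cell RNA and RNA that varies with miR-486 stay open. Both calls ended, with a smaller fold and a wider interval than the 2.06 (1.16 to 2.95) without a covariate. With the miR-451 ratio the fold was close to that value, and at day 25 the call was kept at 1.84 (edgeR adjusted p = 0.036). The lost call thus says little about red blood cell RNA as measured by miR-451. With miR-486, also abundant in red blood cells, the fold was 1.19, so red blood cell RNA is not set aside. More transcript of the locus of miR-191 and miR-425 is argued against by miR-425-5p, at 0.33 with SE 0.33, and miR-191, at -0.26. An effect of status on this arm alone, and preparation order, stay open.

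Of 7 pairs of names with nearly the same counts, 7 lie as overlapping genes in assembly ARS-UCD2.0, where 35 pairs overlap among 1032 miRNA genes. A candidate explanation is reads counted for both of 2 overlapping hairpin genes, and 7 of the 7 pairs overlapped as it needs. The second names hold 5.33% of counts.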
